A study of Mus musculus with 6 samples.

How the data were processed

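RNA-seq libraries from flow-sorted basal epidermal cells of mouse back skin were analysed, 3 from the control group and 3 from the Piezo1 cKO group. Groups and replicate numbers were taken from the sample titles in the labels. The libraries were made from poly(A) RNA with a strand-specific kit, per the labels' protocols. The submitters' processing notes name STAR, DESeq2 and the build GRCm38, without versions. The annotation, the program that counted reads, the use of strand in counting and any filter are not given in the sources used here. Reads from overlapping genes, or from close family members such as Gstm1 and its relatives, the Lce1 genes and the keratins, may therefore be divided in ways that are not known.

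The deposited table holds a normalized count signal per gene and library, never negative, with gene symbols and no test results. That these are read counts divided by a factor per library was read from the values, since low values recur at multiples of a smallest step in each library. The step was taken as the worth of 1 read, and the total divided by it as the approximate depth. Low values, up to 3.5 reads, were within 0.05 of a whole read in 47.1% of cases in cKO replicate 1 and in 86.1% to 90.0% in the other libraries. Between 20 and 100 reads the share was only 9.01% to 13.7%, so whole reads could not be recovered. Part of the factor may vary by gene, or the step may be slightly off, and this was not tested. The analysis planned for whole counts was therefore replaced by the one planned for normalized values. Of 24972 table entries, 7639 were 0 in every library. Another 26 carried names changed into dates by a spreadsheet, 19 of which were tested without being named here.

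Values were tested as log2(value + 1), a scale on which small changes of weakly expressed genes are understated, while a value of 0 in a shallow library can overstate or reverse a change. Genes with a mean of at least 10 normalized counts were kept, 12239 in all. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust empirical Bayes (statmod 1.5.0), all 6 libraries, no covariates, two-sided, and Benjamini-Hochberg adjustment at 0.05. Means are given with the SD over 3 libraries, and log2 fold changes are cKO minus control with limma's SE and 95% interval. The median log2 fold change over all genes was -0.03 and moved to between 0.01 and 0.06 with scaling to library totals, quantile normalization or removal of length and GC trends. Piezo1 was also tested with an exact permutation of the 6 libraries. Depth limits what cKO replicate 1 can show, since 15.2% of the tested genes lay under 3 reads there against 0.270% to 0.490% in the other libraries, and 802 tested genes were listed at 0. These floors cover counting error only.

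Written from textbook knowledge, 38 gene lists were fixed before the data were examined, and 33 with at least 5 tested members were compared with limma's camera (two-sided, preset correlation 0.01, adjusted over the 33). Camera with an estimated correlation, and fry, which tests whether members move one way on balance without comparing them with other genes, were run beside it. Sex-linked genes were left out of this test and are given as levels. Another 5 list members were not matched under the names used. Some list members that the rule for named genes takes are not reported here. Calls adjusted over the list alone use only that list's members. The genes named were chosen by a rule fixed in advance. It takes Piezo1; in each direction the called genes of largest change with groups that do not overlap and a mean of at least 50, or, with fewer than 5 called, those of smallest unadjusted p up to 5; up to 2 members of smallest unadjusted p per list and the 2 most abundant per cell type list; and Krt5, Krt14, Trp63, Krt1 and Krt10 as level references. Names ending in Rik or of the form Gm plus digits were left out of the second part. Genes named beyond the rule, chosen after their values were seen, are Cdh1, Ctgf, Cd207, the T cell genes that passed over their list alone, the markers added in the plot of immune genes (Cd3e to Laptm5, Csf1r and H2-Ab1), Amd1, Amd2 and 1600014C10Rik.

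Gene positions, lengths and GC content came from the GENCODE M21 annotation of GRCm38 and were found for 99.1% of tested genes. The steps were tested on simulated data drawn from the gene means over the 6 libraries and the real depths, with the median dispersion of the controls, which is smaller than the spread seen with cKO replicate 1. There limma called 74% of 100 genes changed 2-fold and 95% of 100 changed 4-fold among 12238 genes, with 3 unchanged genes called. Every simulated gene had the same dispersion and varied independently of the others. These shares therefore do not tell how many changes of such size the real data could reveal. Alternatives planned in advance were the pseudocount, filters, scaling, thresholds, limma-voom, a block for the replicate number, camera with an estimated correlation, fry, and leaving out each library. Library quality weights, the Xist level as a covariate, removal of length and GC trends, quantile normalization and the left-out libraries for single lists, including calls adjusted over a list alone, were added after the data were seen.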

Results

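Poly(A) RNA was sequenced from basal epidermal cells flow-sorted from mouse back skin, with 3 control and 3 Piezo1 cKO libraries. Piezo1 is a mechanically gated cation channel of the plasma membrane. All 6 samples carried the same genotype. It combined p63CreER, a tamoxifen-activated Cre recombinase expressed in basal keratinocytes, with a floxed Piezo1 gene and R26-mTmG, a membrane-targeted fluorescent reporter that switches colour after recombination. Control animals received vehicle, and cKO animals received tamoxifen (3 injections of 20 ug per dose between postnatal days 45 and 52), so exposure to tamoxifen and deletion of Piezo1 went together. The labels number the samples but do not say that each came from a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

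The smallest steps in the normalized counts put the approximate depth at 22.4, 24.5 and 20.8 M reads in control replicates 1, 2 and 3. It was 1.05, 15.6 and 14.2 M reads in cKO replicates 1, 2 and 3. A single read was worth 12.2 normalized counts in cKO replicate 1 and 0.491 to 0.759 in the other libraries, and 3 reads in cKO replicate 1 came to 36.7 normalized counts. That library had 12044 genes above 0, against 15144 to 15388 elsewhere. Ribosomal protein genes took 14.5% of its normalized counts and 6.72% to 8.73% of the others. Its log2 values correlated with those of the other libraries across genes at r = 0.814 to 0.855, while control replicate 1 and cKO replicate 2 reached 0.978 (genes are not independent replicates). Xist, the RNA that silences an X chromosome in female cells, stood at 13994 normalized counts in control replicate 1, 7773 in cKO replicate 1 and 17829 in cKO replicate 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were instead found in control replicates 2 and 3 and cKO replicate 3, where Ddx3y stood at 1722, 2274 and 1317 normalized counts. The sexes were therefore divided unequally between the groups, and each group held more than 1 animal.

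The comparison asked how basal keratinocytes differ in their transcriptome when Piezo1 is deleted, in a series on the structural adaptation of epidermal stem cells to mechanical stress. Piezo1 itself was measured at 1127 ± 336 normalized counts in controls and 448 ± 102 in cKO (SD, n = 3 each). The 3 control libraries gave 806, 1098 and 1476, and the 3 cKO libraries gave 380, 565 and 399. The log2 fold change was -1.31 (SE 0.27, 95% interval -1.93 to -0.68), which is 2.48-fold lower (1.61 to 3.82), and all 3 cKO values lay below all 3 control values. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. With limma the p was 0.00141 and the Benjamini-Hochberg adjusted p was 0.744 over 12239 genes. Adjusted over the list of mechanosensitive and calcium channels alone, Piezo1 passed (adjusted p = 0.0367), and it was the 1 member of the 26 tested that did. It did not pass there without control replicate 2, control replicate 3, cKO replicate 1 or cKO replicate 3, where the smallest adjusted p in the list was 0.114 to 0.168. Piezo1 lies on chromosome 8 at positions 122481698 to 122551329 on the minus strand (GRCm38, ENSMUSG00000014444.17). A value summed over the whole gene cannot separate transcripts that lack the deleted part from intact ones.

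Across the transcriptome no gene passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 603 genes, 180 higher and 423 lower in cKO, where 612 would fall there by chance. limma-voom on approximate reads also called 0 genes, with 679 at an unadjusted p under 0.05. The groups did not overlap at 631 genes with higher and 698 with lower cKO values, 10.9% of genes against 10% by chance. The basal keratins were alike in level. Krt5 stood at 242789 ± 16634 in controls and 243915 ± 20001 in cKO, and Krt14 at 137925 ± 10228 and 151551 ± 45749 (SD, n = 3 each). Trp63, the transcription factor that maintains the basal layer, gave 6247 ± 962 and 8809 ± 1044, a log2 fold change of 0.50 (SE 0.21, 95% interval 0.02 to 0.98). The early suprabasal keratins gave log2 fold changes of 0.99 (SE 0.35) for Krt1 and 0.40 (SE 0.34) for Krt10. None of these 5 genes passed adjustment in limma.

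The genes with the smallest unadjusted p in each direction are given by a rule fixed in advance, and none passed adjustment (adjusted p = 0.744 for each). On the lower side, besides Piezo1, the estrogen receptor gene Esr1 was at 475 ± 53.3 in controls and 214 ± 49.5 in cKO (log2 fold change -1.17, SE 0.24). Tslp, the epithelial alarmin that acts on dendritic and type 2 immune cells, was at 231 ± 72.1 and 72.4 ± 21.4 (-1.67, SE 0.35). The transcription factor Ets1 was at 1774 ± 739 and 508 ± 231 (-1.80, SE 0.40), and Smad3, a mediator of TGF-beta signalling, at 893 ± 289 and 358 ± 91.6 (-1.29, SE 0.30). Esr1 and Tslp each passed when adjusted over their own fixed lists alone, with adjusted p = 0.0152 among 12 estrogen-responsive genes and 0.0370 among 24 cytokines and alarmins. Esr1 did not pass without control replicate 1, control replicate 3 or cKO replicate 3, where the smallest adjusted p in its list was 0.0515 to 0.0850. Tslp passed with cKO replicate 1 left out and with no other library left out, where the smallest adjusted p in its list was 0.0730 to 0.242. On the higher side, the monocarboxylate transporter family member Slc16a6 was at 38.5 ± 5.32 in controls and 181 ± 47.0 in cKO (log2 fold change 2.18, SE 0.33). Gpc3, a cell-surface heparan sulfate proteoglycan, was at 42.2 ± 10.1 and 141 ± 19.6 (1.73, SE 0.32). The transglutaminase gene Tgm7 gave 1.08 (SE 0.22), the glutathione S-transferase gene Gstm1 0.85 (SE 0.19), and Itga7, an integrin subunit that binds laminin, 1.73 (SE 0.38).

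**Figure D1:**
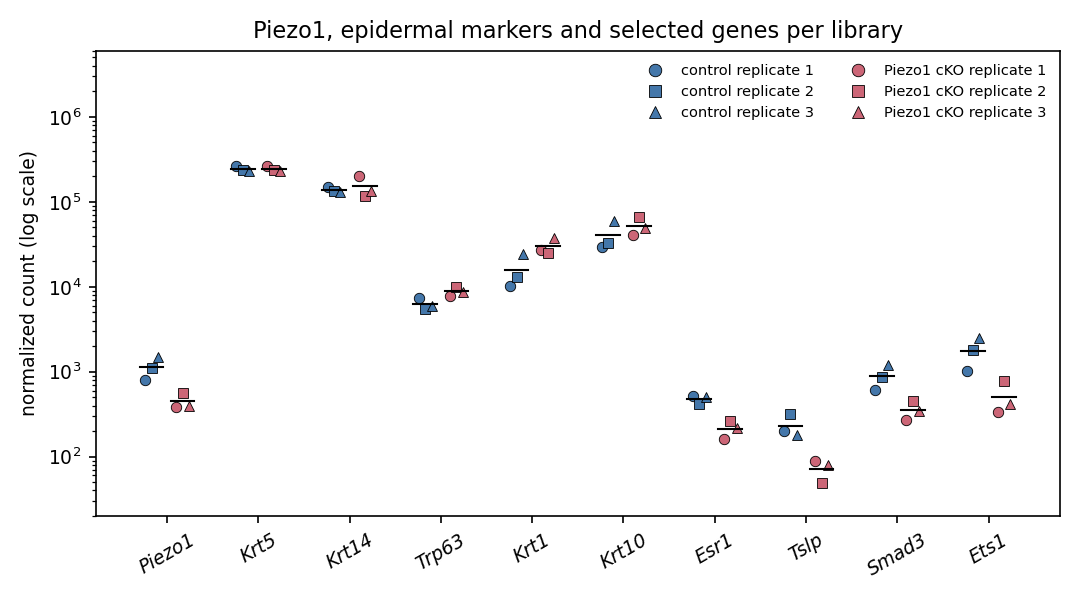
Normalized counts on a log axis for Piezo1, epidermal markers and genes with small unadjusted p, with 1 point per library and black lines at the means of 3 libraries. The 3 Piezo1 cKO libraries lie at 380 to 565 for Piezo1 and the 3 controls at 806 to 1476, while Krt5 and Krt14 overlap between the groups.

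Gene lists fixed in advance were then compared as groups with camera, which asks whether a list's members moved more than other genes. Of 33 lists tested, 16 passed an adjusted p of 0.05 at the preset correlation of 0.01 between genes, 6 higher and 10 lower in cKO. With a correlation estimated from the data none passed (smallest adjusted p = 0.489), and none passed in fry (smallest adjusted p = 0.359). No list had a member that passed over all genes tested.

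Cell-cell and cell-matrix adhesion genes lay lower in cKO. Of the 20 adherens and tight junction genes tested, all 20 had lower fitted values and 8 had an unadjusted p under 0.05 (median log2 fold change -0.62, camera adjusted p = 3.0e-07, adjusted p = 0.489 with an estimated correlation). Among them, the tight junction claudin Cldn4 was at 3685 ± 2330 normalized counts in controls and 872 ± 208 in cKO (-1.89, SE 0.46). E-cadherin, Cdh1, was at 16528 ± 4631 and 9542 ± 2653 (-0.79, SE 0.30). Of 24 integrin focal adhesion genes, 19 were lower and 6 of these had an unadjusted p under 0.05 (median -0.45, camera adjusted p = 4.0e-05, 0.489 as the adjusted p with an estimated correlation). Itgb6, the beta subunit of an integrin that activates latent TGF-beta, gave -1.78 (SE 0.50), the adaptor Bcar1 -0.88 (SE 0.23) and Itgb1, the common beta subunit of basal keratinocyte integrins, -0.94 (SE 0.28). Hemidesmosome and basement membrane genes were lower in 17 of 20 (median -0.31, camera adjusted p = 0.00369, adjusted p = 0.489 with an estimated correlation), with the integrin gene Itga6 at -0.70 (SE 0.36). Desmosome genes were lower in 11 of 12 and did not pass (median -0.21, camera adjusted p = 0.112), though they did without control replicate 1 (0.0431, median -0.28) or cKO replicate 2 (0.0382, median -0.38). Without control replicate 3 (median -0.06) or cKO replicate 1 (median -0.11), 8 of the 12 were lower. Adjusted over each of these 4 lists alone, 0 genes passed. Without control replicate 1 that number was 6 for adherens and tight junctions and 3 for focal adhesions, all lower, and without cKO replicate 2 it was 8 and 7, all lower.

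Actomyosin genes were lower in 27 of 32, 4 of them at an unadjusted p under 0.05 (median -0.27, camera adjusted p = 0.00126, adjusted p = 0.490 with an estimated correlation). The nonmuscle myosin heavy chain gene Myh14 gave -0.82 (SE 0.29) and the tropomyosin gene Tpm4 -0.65 (SE 0.25). Targets of SRF and its coactivator MRTF, which respond to actin assembly, were lower in 18 of 23 (median -0.36, camera adjusted p = 0.0215, adjusted p = 0.490 with an estimated correlation), with Tpm1 at -1.15 (SE 0.46). YAP and TAZ targets were lower in 18 of 23 (median -0.23, camera adjusted p = 0.0482, adjusted p = 0.489 with an estimated correlation). In that list F3, tissue factor, was at 979 ± 779 in controls and 180 ± 77.6 in cKO (-2.12, SE 0.68), whereas Ctgf, a widely used YAP target, was at 136 ± 39.8 and 228 ± 53.7 (0.76, SE 0.30). The mechanosensitive and calcium channels, Piezo1 among them, were lower in 17 of 26 and did not pass (median -0.17, camera adjusted p = 0.0805). Their median was -0.27 without cKO replicate 3. They passed with a mean of at least 50 (adjusted p = 0.0121, median -0.31), the same filter with a minimum of CPM (0.0120) and without control replicate 2 (0.0373, median -0.15). Trpv3, a warmth-sensitive channel of keratinocytes, gave -1.34 (SE 0.50). Genes of the nuclear lamina and of its links to the cytoskeleton were lower in 13 of 19 (median -0.15, or -0.04 without cKO replicate 1, camera adjusted p = 0.363).

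These lists did not separate every library. The median of the adherens and tight junction list against the control mean was -0.33 in control replicate 1, 0.04 in control replicate 2 and 0.32 in control replicate 3, and -1.02, -0.23 and -0.62 in cKO replicates 1, 2 and 3. The suprabasal list stood at -1.24, 0.17 and 1.31 in control replicates 1, 2 and 3, the controls ranking as in the adherens and tight junction, focal adhesion, hemidesmosome, actomyosin and SRF lists, and at -1.10, -0.89 and -0.78 in cKO replicates 1, 2 and 3. Without the shallow cKO replicate 1 the median of the junction list was -0.41 instead of -0.62 and that of the focal adhesion list -0.26 instead of -0.45, both still past the threshold at the preset correlation. The actomyosin median was -0.17 with quantile normalization. Leaving out control replicate 3 ended the call for SRF and MRTF targets (adjusted p = 0.106) with a median of -0.37, close to the -0.36 of all libraries, and testing all genes without a filter also ended it (0.102, median -0.36). Leaving out cKO replicate 3 ended it for them (0.187, median -0.24) and for the hemidesmosome list (0.109, median -0.22). The YAP and TAZ call, near the threshold with all libraries, ended without control replicate 1 (0.0869, median -0.22), control replicate 3 (0.106, -0.24), cKO replicate 1 (0.131, -0.14), cKO replicate 2 (0.0871, -0.35) or cKO replicate 3 (0.109, -0.31). It also ended with no filter, with stricter filters and with quantile normalization (adjusted p = 0.0562 to 0.0716), and the median stayed negative in each case.

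**Figure D2:**
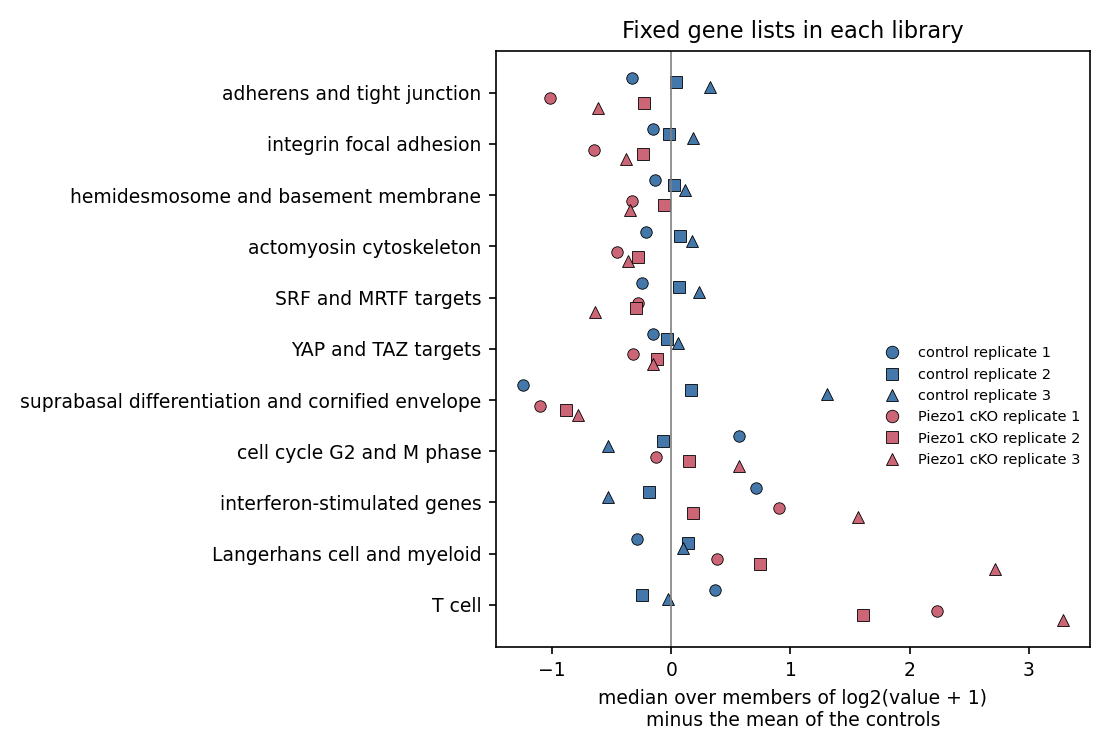
Median over the tested members of each list of log2(value + 1) minus the mean of the 3 controls, with 1 point per library and small vertical offsets for legibility. In the adherens and tight junction list control replicate 1, at -0.33, lies below cKO replicate 2, at -0.23, and in the T cell list all 3 cKO libraries lie at 1.61 or above.

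Suprabasal differentiation and cornified envelope genes were lower in 25 of 29 (median -0.93, camera adjusted p = 4.5e-04, adjusted p = 0.633 with an estimated correlation). The late cornified envelope gene Lce1a1 stood at 7.18, 82.7 and 591 normalized counts in control replicates 1, 2 and 3, and at 0, 3.74 and 8.18 in the cKO libraries, while the early gene Krt1 was higher in cKO. Control replicate 1 had the lowest list median of all libraries and control replicate 3 the highest. Without control replicate 3 the call was lost (adjusted p = 0.370) and the median was -0.38, and without control replicate 1 the median was -1.50. Basal keratinocyte identity genes did not pass (15 of 22 lower, median -0.14, camera adjusted p = 0.112), except without cKO replicate 1 (0.00738, median -0.18), and the median was -0.23 without control replicate 1. Within that list Sostdc1, an inhibitor of BMP and Wnt signalling, was at 983 ± 135 in controls and 2233 ± 928 in cKO (1.10, SE 0.31). Stress and wound keratinocyte genes went both ways (13 higher and 14 lower, camera adjusted p = 0.956), with the connexin gene Gjb6 at 2.23 (SE 0.54) and the wound keratin gene Krt16 at -1.23 (SE 0.36).

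Genes of lymphocytes and antigen-presenting cells lay higher in cKO. Of the 12 T cell genes tested, 11 had higher fitted values and 9 had an unadjusted p under 0.05 (median log2 fold change 2.28, camera adjusted p = 1.2e-10, p = 0.0384 and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, 8 genes rose. They were the signalling subunits of the T cell receptor complex Cd3d, Cd3e, Cd3g and Cd247, the receptor subunit Il2rb, the surface protein Cd7, and Nkg7 and Ctsw of cytotoxic lymphocytes. The receptor chain genes Trac, Trdc, Trbc1 and Trbc2 were not matched under these names. The number of genes that rose over the list alone was 12 without cKO replicate 1, 6 without control replicate 2, 6 without control replicate 3 and 0 without cKO replicate 3. The levels were low. Only 7 of the 12 genes averaged at least 10 normalized counts in controls. The others passed the filter through their cKO values, which favours a higher median and a smaller camera p. Cd3e was at 22.4 ± 9.12 normalized counts in controls and 99.4 ± 35.5 in cKO (2.12, SE 0.50), Cd3g at 19.0 ± 7.73 and 102 ± 58.4 (2.28, SE 0.54), and Cd7 at 17.0 ± 9.19 and 117 ± 69.4 (2.63, SE 0.62). Ptprc, the pan-leukocyte antigen CD45, was at 27.6 to 30.6 in the 3 controls and was listed at 0 in cKO replicate 1, with 92.9 and 263 in cKO replicates 2 and 3. Per library, the T cell list median was 2.23, 1.61 and 3.29 in cKO replicates 1, 2 and 3, and 0.37 or less in each control.

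Langerhans cell and myeloid genes were higher in 13 of 15, with 7 at an unadjusted p under 0.05 (median 1.16, camera adjusted p = 4.3e-06, adjusted p = 0.489 with an estimated correlation) and 0 adjusted over the list alone, a number that was 3 without cKO replicate 1 and 6 without cKO replicate 2, all higher. The MHC class II invariant chain gene Cd74 was at 698, 667 and 737 normalized counts in the controls and at 1163, 1008 and 4490 in cKO replicates 1, 2 and 3. Cd207, langerin, was at 87.3, 222 and 216 in the controls and at 170, 172 and 1035 in the cKO libraries. The list median was 0.38, 0.74 and 2.72 in cKO replicates 1, 2 and 3, and the median change was 0.71 when genes under the filter were included. Interferon-stimulated genes were higher in 22 of 24, 3 of them at an unadjusted p under 0.05 (median 0.95, camera adjusted p = 5.7e-08, adjusted p = 0.489 with an estimated correlation). Oas1a, a sensor of double-stranded RNA, gave 1.66 (SE 0.54) and the ubiquitin-like modifier Isg15 1.47 (SE 0.60). The interferon list also stood at 0.71 in control replicate 1, above cKO replicate 2 at 0.18. Its median change was 0.53 without cKO replicate 3 and 1.41 without control replicate 1, and the list passed in both cases. Cytokines and alarmins were lower in 16 of 24 and did not pass (median -0.20, camera adjusted p = 0.202; median -0.01 without cKO replicate 1 and -0.34 without control replicate 3), with Il34, a growth factor for Langerhans cells, at 599 ± 97.1 in controls and 1037 ± 345 in cKO (0.76, SE 0.26).

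**Figure D3:**
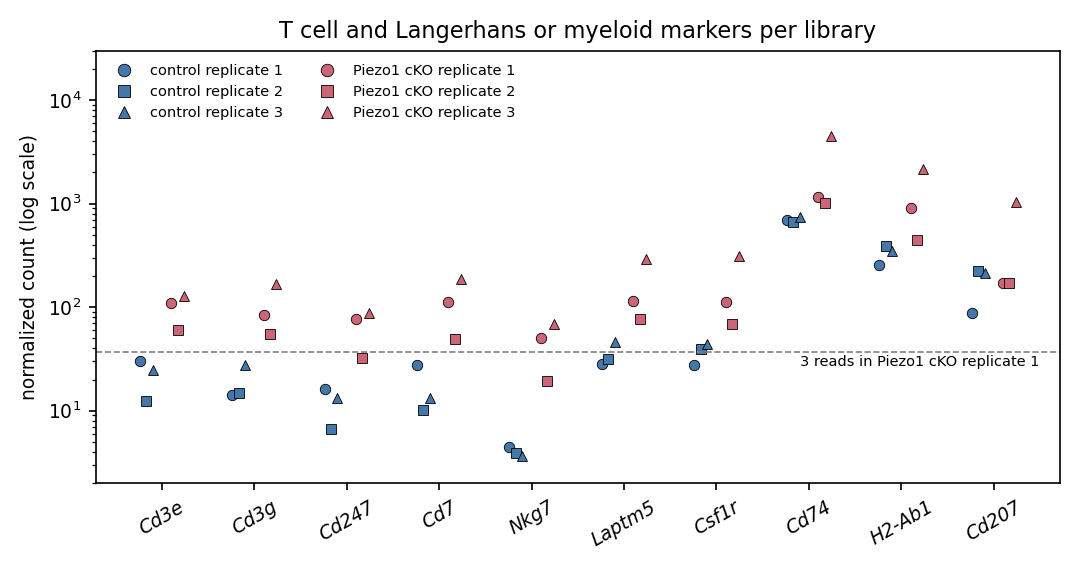
Normalized counts on a log axis for T cell markers (Cd3e to Nkg7) and Langerhans or myeloid markers (Laptm5 to Cd207), with 1 point per library. The dashed line marks the worth of 3 reads in Piezo1 cKO replicate 1, 36.7, and Piezo1 cKO replicate 3 holds the highest value of every gene shown.

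Among markers of other skin cells, hair follicle stem cell and outer root sheath genes were higher in 15 of 20 (median 0.27, camera adjusted p = 0.00816) and fibroblast genes in 6 of 8 (median 0.36, camera adjusted p = 0.0426). Sebaceous gland genes were lower in 16 of 18 (median -0.60, camera adjusted p = 0.0440). With an estimated correlation the adjusted p was 0.489 for the first list, 0.489 for fibroblasts and 0.649 for sebaceous genes. Krt79, a keratin of the upper follicle and its ducts, was at 3604 ± 657 in controls and 6213 ± 1482 in cKO (0.77, SE 0.25). The sebaceous call ended without control replicate 2 (adjusted p = 0.497, median -0.25), control replicate 3 (0.286, -0.40), cKO replicate 1 (0.0622, -0.49) or cKO replicate 2 (0.388, -0.42), and also with stricter filters (0.125), quantile normalization (0.0512) or the Xist level as a covariate (0.330). Without control replicate 1 its median was -1.27. That for fibroblasts ended without control replicate 2 (0.184, median 0.31) or cKO replicate 3 (0.153, 0.22), and also with library totals (0.0563), no filter (0.129), length and GC trends removed (0.0578) or quantile normalization (0.0596). Its median was 0.55 without control replicate 3 and 0.66 without cKO replicate 2. That for the follicle ended without control replicate 1 (0.162, median 0.34) or cKO replicate 3 (0.0868, 0.05), and its median was 0.41 to 0.47 without control replicate 3 or cKO replicate 2, with quantile normalization or with the Xist covariate. Hair shaft genes (5 tested, camera adjusted p = 0.493) and Merkel and Schwann cell genes (5 tested, camera adjusted p = 0.207) did not pass. Lists of endothelial, erythroid, melanocyte, and adipocyte and muscle genes had 3, 2, 3 and 1 members above the filter and were not tested as groups.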

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

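Piezo1 stayed lower under each alternative, with a log2 fold change of -1.53 to -1.09 over the 6 left-out libraries (adjusted p = 0.378 to 0.978) and -1.31 to -1.17 over the others without quality weights (0.625 to 0.924). With library quality weights, added after the data were seen like the Xist, length and GC, and quantile alternatives, it was -1.40 and passed (adjusted p = 0.0108). Those weights also called 1568 genes instead of 0, 623 higher and 945 lower, and put 3827 genes instead of 603 at an unadjusted p under 0.05; they ran from 0.111 for cKO replicate 1 to 8.98 for control replicate 2. With the Xist level as a covariate 306 genes lay at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 1 genes called, 0 to 1 of them lower, and 169 (without control replicate 3) to 1574 (without cKO replicate 2) genes at an unadjusted p under 0.05, with 220 without control replicate 2 and 1029 without control replicate 1. The 1 gene, without cKO replicate 2, was Amd1. Of the biology and context lists, 11 passed camera at the preset correlation, 0 with an estimated correlation, 0 in fry, and 5 (without cKO replicate 3) to 13 with a library left out, with 7 without control replicate 3. Of the cell type lists, 5 passed, with 3 under quantile normalization, 0 with an estimated correlation, 0 in fry and 3 to 4 with a library left out (3 without control replicate 2 or cKO replicate 3). The fitted Ptprc change, -0.06, turned positive at 0.029 with library totals, 0.57 with a pseudocount of 5, 0.25 with length and GC trends removed, 0.91 with quantile normalization, 0.57 with the Xist covariate, 2.71 with quality weights, 2.05 with limma-voom and 2.38 without cKO replicate 1, where it is listed at 0 in a library of 1.05 M reads (-1.65 without cKO replicate 3). The cause of the other shifts was not tested. Size factors recomputed by median ratio were equal for all libraries and moved nothing, so they test nothing. limma-voom used values divided by the worth of 1 read, and planned tests on whole counts were not run because whole reads could not be recovered.

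With the replicate number as a block, 0 genes were called, 848 lay at an unadjusted p under 0.05, and 12 biology and context lists, the circadian clock list among them (adjusted p = 0.0290), and 5 cell type lists passed. Deviations of same-numbered libraries from their group means correlated across genes at 0.09, -0.15 and 0.07, and not every library correlated best with its own number. This gave no sign that the numbers pair the samples. It cannot exclude a pairing, since deviations from the mean of so few libraries depend on each other and cKO replicate 1 was shallow.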

Other observations

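Genes of the G2 and M phases were higher in 24 of 31 (median log2 fold change 0.23, camera adjusted p = 0.00736, adjusted p = 0.649 with an estimated correlation), with the mitotic kinase gene Aurka at 133 ± 67.7 normalized counts in controls and 227 ± 75.9 in cKO (SD, n = 3 each; 0.83, SE 0.41). The call ended without control replicate 3 (adjusted p = 0.918, median -0.05) or cKO replicate 3 (0.408, 0.05), and the median was 0.47 without control replicate 1. S phase genes did not pass (17 of 26 higher, median 0.16, camera adjusted p = 0.172), except without control replicate 2 (0.0226, median 0.27) or cKO replicate 1 (0.0263, median 0.23). Their median was 0.27 without control replicate 1 and 0.29 without cKO replicate 2, and it turned negative without control replicate 3 (-0.02) or cKO replicate 3 (-0.05). Cholesterol synthesis genes were lower in 16 of 23 (median -0.36, camera adjusted p = 0.0237, adjusted p = 0.573 with an estimated correlation), with the sterol oxidase gene Msmo1 at -0.98 (SE 0.34). That call ended without control replicate 3 (adjusted p = 0.28, median -0.18), cKO replicate 1 (0.0555, -0.18) or cKO replicate 3 (0.103, -0.35), and the median was -0.22 with length and GC trends removed and -0.19 with quantile normalization. Targets of p53 were lower in 15 of 22 (median -0.20, camera adjusted p = 0.0440, adjusted p = 0.489 with an estimated correlation), with the stress-response gene Sesn2 at -1.42 (SE 0.47). The p53 call ended without control replicate 1 (0.304, median -0.08), cKO replicate 2 (0.0749, -0.16) or cKO replicate 3 (0.113, -0.26), and also with no filter (0.0632) or stricter filters (0.0544 and 0.0545), and the median was -0.10 with length and GC trends removed and -0.13 without control replicate 2. Lists that did not pass were the circadian clock (camera adjusted p = 0.0805), immediate early genes (0.172), Wnt (0.40), Notch (0.956), dermal matrix enzymes (0.462), unfolded protein response (0.363), glycolysis and hypoxia (0.903) and estrogen-responsive genes (0.632). Among these, the clock list passed with length and GC trends removed (0.0478), without control replicate 3 (0.0392) and without cKO replicate 2 (0.0150), and the immediate early list passed without control replicate 1 (0.00463). The Notch list had a median of -0.08 where camera pointed upwards, and the glycolysis list a median of 0.01 where it pointed downwards. Leaving out 1 library moved these medians between -0.13 and 0.10 for Notch and between -0.14 and 0.10 for glycolysis.

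Single genes in these lists also stood apart without passing adjustment (limma, adjusted p = 0.744 each). The Wnt receptor gene Fzd10 was at 405 ± 134 normalized counts in controls and 893 ± 223 in cKO (1.16, SE 0.30), and the matrix protease gene Mmp2 at 134 ± 67.3 and 373 ± 66.2 (1.57, SE 0.37). The Notch feedback gene Nrarp gave 0.66 (SE 0.23) and the Notch ligand gene Dll1 -0.77 (SE 0.30). The melanocyte and macrophage glycoprotein gene Gpnmb was at 42.1 ± 9.41 and 111 ± 19.1 (1.38, SE 0.33) and passed over its list of 3 tested genes alone (adjusted p = 0.0106), but not without control replicate 1, control replicate 2 or cKO replicate 2, where the smallest adjusted p in the list was 0.0516 to 0.0687. The smallest unadjusted p of all genes, 8.3e-05, belonged to the unnamed gene 1600014C10Rik, at 358 ± 48.2 and 1628 ± 608 (2.13, SE 0.28), which was chosen after its values were seen. Amd1, an enzyme of polyamine synthesis, was at 356, 344 and 677 in the controls and at 0, 167 and 0 in cKO replicates 1, 2 and 3. It has a near-identical copy, Amd2, which was at 2774 ± 247 and 2695 ± 153, so how reads were divided between the copies is uncertain.

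In what follows, the tests that leave out cKO replicate 1 and the counts of genes over other splits of the libraries without weights were chosen only after the results were seen. The first pattern is the lower level of 5 lists in cKO, namely adherens and tight junctions, focal adhesions, hemidesmosomes, actomyosin and SRF targets. The shallow cKO replicate 1 was tested by leaving it out, and 5 of the 5 lists stayed past the threshold in camera at the preset correlation, with medians of -0.41, -0.26, -0.22, -0.27 and -0.41 in the order named, against -0.62, -0.45, -0.31, -0.27 and -0.36 with it, so that library carries part of the size in the first 3. The same number, 5, passed after removal of length and GC trends, and 5 with the Xist level as a covariate for the unequal sexes. Without control replicate 3, the control highest in these lists, 4 passed; the SRF list did not (adjusted p = 0.106), though its median, -0.37, was close to the -0.36 of all libraries. The calls at the preset correlation thus did not rest on any 1 of the 4 alone, except that for SRF targets. This cannot rule the 4 out as sources, since the 5 lists were taken up after they had passed. Some share genes, and none passed without the preset correlation. Effects of tamoxifen and of Piezo1 deletion stay open because the design joins them. So does a smaller share of differentiated cells, since the suprabasal list ranks the controls in the same order as these 5 lists. Yet control replicate 1, lowest in the suprabasal list (-1.24), exceeded every cKO library for focal adhesions, actomyosin and SRF targets. It stood at -0.15, -0.21 and -0.24 in these lists, and the nearest cKO library at -0.24, -0.28 and -0.28. The gaps were smaller than the spread among the controls, so they do not decide the question. In the junction and hemidesmosome lists control replicate 1 lay below cKO replicate 2. Krt1 was higher in cKO (0.99), though 25 of the 29 suprabasal genes tested were lower.

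The second pattern is the higher level of T cell and Langerhans genes. A candidate explanation is more lymphocytes among the sorted cells of the cKO libraries. A second list was written for lymphocytes before its values were seen and shares no tested gene with the fixed lists. It had a median log2 fold change of 1.03, just over the bound of 1 set for it. Of its 18 tested genes, 15 were higher (83.3%), 1 of them at an unadjusted p under 0.05 in limma. Camera gave p = 1.9e-05, or p = 0.143 with an estimated correlation. The median of this second list was 0.21, 0.65 and 2.17 in cKO replicates 1, 2 and 3, so it rests mostly on cKO replicate 3. The Langerhans and myeloid list ranked these libraries the same way (0.38, 0.74 and 2.72), whereas the T cell list gave 2.23, 1.61 and 3.29. The second list therefore cannot tell lymphocytes from other leukocytes. A flow sort for basal cells would be expected to remove such cells. The T cell list median lay above every control in each cKO library, most so in cKO replicate 3, but the level of these genes was low. In cKO replicate 3 Cd3e was at 128 normalized counts, against a control mean of 22.4. Ptprc, which the Langerhans and myeloid list also holds, was at 263 there, against 29.4. Ptprc was listed at 0 in cKO replicate 1. Of the 12 T cell genes, 2 are held by another fixed list and 7 averaged at least 10 normalized counts in controls. The T cell median was 2.55 without cKO replicate 1 and 2.44 with the Xist covariate. The size of the rise thus did not rest on the shallow library or on the Xist level alone. This cannot rule out either as a source, since the list was taken up after it had passed. Whether the number of immune cells in the skin or the purity of the sort differed stays open, as no unsorted sample was analysed here.

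The third pattern is the number of genes and lists that stood apart. With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. For genes past the adjusted threshold the real split gave 0 and the highest other 6; against 0 all 10 splits give as many by construction, which says nothing about chance. That other split set the 3 libraries with high Xist against the rest. At an unadjusted p under 0.05 the real split gave 603 genes and the highest other 1186 (3 of 10 as many), for lists 16 and 17 (2 of 10), and with library quality weights 1568 and 4288 genes (2 of 10). The split with 4288 genes set control replicate 1 with cKO replicates 2 and 3, and without weights it called 0 genes and 10 lists.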
